A study of Mus musculus with 6 samples.

How the data were processed

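RNA was sequenced from monocytes sorted out of B16F10 melanoma tumours of mice, in 6 libraries: 3 after lipid nanoparticles with GFP mRNA (LNP-GFP) and 3 after lipid nanoparticles with Gsdme mRNA (LNP-Gsdme). Per the labels' protocols, RNA was extracted with a column kit, treated with DNase, purified on beads and made into paired-end TruSeq libraries. Groups were taken from the treatment label of each sample and replicate numbers from its title.

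The authors deposited 1 table of 56980 Ensembl genes with positions, and with raw counts and FPKM for each library, per the file headers. The build is GRCm39 per the submitters' processing notes, and the aligner, the counting tool, its strand setting and the annotation release are not given in the sources used here. Reads shared between paralogs, overlapping genes or antisense partners therefore could have been split, dropped or counted for either gene, which leaves families such as Ly6c, Oas1, Trim30, Phf11, Slfn, Gbp, Tgtp and H2 uncertain. The deposited counts are whole numbers that were not normalized. The deposited FPKM values are the same counts divided by a gene length and the library total, which was checked on 11356 genes with over 50 counts in each library (implied lengths differed between libraries by at most 0.00178%), and they were not used in tests. Gene positions are those of the deposited table. Genes without a symbol (1542 in the table, holding 0.112 to 0.150% of counts per library) stayed in the tests under their identifiers.

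Total counts were 20233559 to 22932095 in LNP-GFP and 15991826 to 18751784 in LNP-Gsdme, and 22875 to 24383 genes were detected per library. At this depth a gene at 1 CPM has about 16.0 to 22.9 counts per library, so counting error is large for genes near the low-count filter.

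Counts were analysed in R 4.3.3 with edgeR 4.0.16: low-count genes were removed with filterByExpr by group, which left 16010, libraries were scaled with TMM factors (0.980 to 1.04), and groups were compared with the robust quasi-likelihood test. P-values were adjusted with the Benjamini-Hochberg method, and genes with an adjusted p below 0.05 were called as having risen or fallen. The biological coefficient of variation was 0.193. CPM values were taken over the library totals of the tested genes multiplied by the TMM factors. Log2 fold changes are LNP-Gsdme over LNP-GFP. Shares of mitochondrial and ribosomal protein counts were compared with an exact permutation test over the 20 assignments of the libraries.

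Gene lists were fixed before the data were examined: 17 functional lists, 2 quality lists and 14 lists of cell type markers, with 795 symbols, of which 793 were matched (9 through another symbol, from a RefSeq table of assembly GRCm38.p6 used for names only). Lists with at least 5 tested members were tested with camera from limma 3.58.1, two-sided, on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Adjustment was over the functional and quality lists together and over the marker lists apart. The members called were also counted with p-values adjusted over the list alone. The type I interferon list shares 1 gene each with the chemokine, pyroptosis and Ly6C-high monocyte lists. The quantity behind the spread of a list is the median absolute deviation of its members' log2 fold changes, scaled to match an SD.

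Genes were named by a rule fixed before the data were examined. It took Gsdme, Slc6a8 and Ckb. It took the 10 largest rises and the 10 largest falls among called genes with an average log2 CPM of at least 2 and no overlap between the groups, leaving out predicted gene models, pseudogenes and immunoglobulin or T cell receptor segments. It took the 2 called members with the smallest p of each functional and quality list, or the 1 with the smallest p where none was called, with 6 for the type I interferon list and 4 for the other interferon and both MHC lists. It took the 2 members of each marker list with the highest mean CPM. For each list, 1 called member moving against the list's median could be added as an exception. The rule named 98 genes, and any other gene in the text was chosen after its values were seen. Values of some single list members are not reported here.

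The alternatives fixed beforehand were DESeq2 1.42.0, other normalizations (RLE, upper quartile, library size only), limma-voom, no low-count filter, a stricter filter (a mean of at least 1 CPM and at least 10 counts in 3 libraries), edgeR without robust fitting, the replicate number as a block, stricter thresholds, camera with an estimated correlation, the rotation test fry and each library left out in turn. After the data had been seen, a comparison of LNP-GFP 1 alone with the 3 LNP-Gsdme libraries was added, because LNP-GFP 3 lay midway between the other LNP-GFP libraries. That position was measured by predicting each library as a weighted mean of each pair of others, over genes with an expected count of at least 100. The squared residual of each gene was divided by its variance from counting noise. The median over genes was taken relative to that of counting noise alone.

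The rule for the technical explanations of the interferon result was revised several times after the values had been seen. The bound of 0.5 log2 units was first applied to the difference of the medians alone, which excluded a larger share of monocyte RNA and a T cell source. Versions without shared genes and with a bootstrap error were also tried for the share of monocyte RNA, and excluded it too. A version that asked for 0.5 plus the spread excluded neither. The rule used here asks the difference to exceed both 0.5 and the median absolute deviation of the comparison list's members, for monocyte, T cell and NK cell markers alike. The T cell difference met this rule only against LNP-GFP 1 and 3, with LNP-GFP 2 left out, and T cells are not taken as excluded. With all libraries the difference to the T cell median was 0.278, under the bound, and against LNP-GFP 2 and 3, a comparison added last, the T and NK cell medians were above the interferon median.

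The fit was tested on simulated counts with the means and library sizes of these libraries, with changes placed in genes of an average log2 CPM above 2. For 3 against 3 libraries (15758 genes) it called 82 of 100 genes changed 2-fold and 22 of 100 changed 1.5-fold, with 3 false calls. Without LNP-GFP 3 (15861 genes) it called 65 of 100 and 15 of 100, with 2 false calls. Each was 1 draw in which no simulated library was built to lie between others. These values therefore do not describe how calls in the real libraries depend on LNP-GFP 3. In the list test 1 list was raised 1.4-fold, and it was the only 1 called. Simulated genes were drawn independently, whereas the estimated correlation within the type I interferon list was 0.199. The simulation therefore cannot show how often correlated lists are called falsely. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.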

Results

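Gene expression was measured by RNA sequencing in monocytes sorted from mouse B16F10 melanoma tumours, a transplanted skin tumour line, as cells positive for CD11b, high for Ly6C and negative for Ly6G. Ly6C-high monocytes are the inflammatory monocytes that leave the blood and mature in tissues, and the exclusion of Ly6G removes neutrophils. Tumours had received lipid nanoparticles (LNP) carrying mRNA for green fluorescent protein (LNP-GFP, 3 libraries) or for gasdermin E (LNP-Gsdme, 3 libraries). Gasdermin E is a pore-forming protein that, once cleaved, starts pyroptosis, a lytic form of cell death. The series asked how tumour monocytes change after delivery of gasdermin E mRNA, with type I interferon signalling and creatine as its topics. The totals were 22932095, 22323501 and 20233559 counts in LNP-GFP 1 to 3. They were 18015501, 15991826 and 18751784 counts in LNP-Gsdme 1 to 3. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical.

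Gsdme itself (chromosome 6, 50165868 to 50240842, GRCm39) was low in the sorted monocytes of both groups. It reached 2.79, 4.44 and 3.95 CPM (counts scaled by library size) in LNP-GFP 1 to 3, and 3.43, 2.68 and 3.19 CPM in LNP-Gsdme 1 to 3. The log2 fold change was -0.26 ± 0.22 (SE, n = 3 per group; edgeR quasi-likelihood adjusted p = 0.450). No rise of Gsdme was detectable in the sorted cells. Whether counts of the gene would include a delivered mRNA depends on its sequence, which is not given in the sources used here.

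In the sorted fraction from LNP-Gsdme tumours, lists of interferon-stimulated, MHC class I and pyroptosis genes were higher, and lists of MHC class II, ribosomal protein and mitochondrial genes were lower. These calls rest on a preset correlation, and with an estimated correlation 0 lists passed (lowest adjusted p = 0.213). Markers of NK and T cells were higher in the same libraries (median log2 fold changes 0.73 and 0.53), and markers of fibroblasts and melanoma cells were lower (-1.33 and -1.64). In all, 1008 genes rose and 851 fell among 16010 tested (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p below 0.05), of which 226 and 288 changed at least 2-fold. These counts depended on LNP-GFP 3, whose profile lay midway between those of LNP-GFP 1 and LNP-GFP 2. Without that library 64 genes rose and 24 fell, 83 of them among the 1859 genes above. The drop was not particular to it: 107 rose and 46 fell without LNP-Gsdme 1, and 119 and 68 without LNP-Gsdme 2. Without LNP-GFP 1 the counts were larger, at 1625 and 1216. All 1857 of the 1859 genes that could be tested without LNP-GFP 3 kept their direction. That was all but certain beforehand, because the groups did not overlap in any of the 1859 genes, so it is no sign of robustness.

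The genes with the largest rises included Ifi44, Ly6c2, Tlr4 and Gzma. Ifi44 (chromosome 3, 151436559 to 151455597), an interferon-induced gene, rose by a log2 fold change of 2.82 ± 0.22 (SE, n = 3 per group; adjusted p = 0.00440). Ly6c2 (chromosome 15, 74980007 to 74983819), which encodes the Ly6C antigen used in the sort, rose from 245 ± 29.7 to 1543 ± 271 CPM (SD, n = 3; log2 fold change 2.66, adjusted p = 0.00219). Both groups were sorted as high for this antigen, so the sorted fractions may differ in purity or gate, which was not tested. Tlr4, the lipopolysaccharide receptor, rose from 10.9 ± 2.33 to 68.9 ± 10.1 CPM (SD, n = 3; adjusted p = 0.00292). Lipg, endothelial lipase, rose from 10.5 ± 2.99 to 67.1 ± 5.30 CPM (SD, n = 3; adjusted p = 0.00460). Slfn4, Pou3f1, Slc36a1 (a lysosomal amino acid transporter), Phf11a and Trim30b rose by log2 fold changes of 2.59, 2.42, 2.16, 2.14 and 2.10. Gzma, a granzyme of NK and cytotoxic T cells, rose by 2.35 ± 0.36 on the log2 scale (SE, n = 3 per group; adjusted p = 0.0173). Ly6c2, Phf11a, Trim30b and Slfn4 have close paralogs, so their counts are uncertain where reads could fit more than 1 copy.

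The genes with the largest falls included Thbs4, Eln, Cilp, Smoc2 and Podn. Thbs4 (chromosome 13, 92888098 to 92931326), a matricellular protein of connective tissue, went from 45.2 ± 10.5 to 5.27 ± 0.227 CPM (SD, n = 3; log2 fold change -3.10, adjusted p = 0.00231). Eln, which encodes elastin (chromosome 5, 134731447 to 134776177), went from 110 ± 16.4 to 14.3 ± 5.11 CPM (SD, n = 3; log2 fold change -2.95, adjusted p = 0.00557). Cilp, Smoc2 and Podn, which encode further matrix proteins, had log2 fold changes of -2.69, -2.61 and -2.45. Cpz, C1qtnf3 and Pcsk5 had log2 fold changes of -2.76, -2.42 and -2.36, and all 6 passed the test. Mtss2 (-3.43) and Slc7a11 (-2.32), the cystine transporter subunit, passed too but varied widely among the controls. Slc7a11 stood at 262, 947 and 601 CPM in LNP-GFP 1 to 3 and at 147, 107 and 108 CPM in LNP-Gsdme 1 to 3. The summed melanoma markers stood at 442, 2041 and 1270 CPM in LNP-GFP 1 to 3 and at 438 ± 379 CPM in LNP-Gsdme (SD, n = 3). For this sum the groups overlapped: LNP-Gsdme 3 reached 875 CPM, above LNP-GFP 1, while LNP-Gsdme 1 and 2 lay below every LNP-GFP library. Slc7a11 was not raised along with the sum in LNP-Gsdme 3 (108 CPM, against 147 and 107 CPM in LNP-Gsdme 1 and 2). In the same libraries the summed fibroblast markers stood at 11312, 12561 and 11899 CPM in LNP-GFP 1 to 3 and at 3800, 2894 and 7162 CPM in LNP-Gsdme 1 to 3.

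Type I interferon-stimulated genes were the group with the strongest test by camera with the preset correlation. By fry the mitochondrial and ribosomal protein lists had smaller unadjusted p-values (0.000351 and 0.000418 against 0.000530). Of 63 tested, 32 rose, 0 fell and 31 did not pass, and 37 rose when adjusted over the list alone. Slfn4, an interferon-induced gene of myeloid cells, rose from 299 ± 42.2 to 1802 ± 30.6 CPM (SD, n = 3; adjusted p = 0.000897). Phf11d rose from 45.2 ± 2.79 to 156 ± 5.77 CPM (SD, n = 3; adjusted p = 0.000897). Ddx60, Oas1g, Trim30d and Oas1a rose as well, and the Oas1 genes are known to sense double-stranded RNA. They rose by log2 fold changes of 1.65, 1.34, 1.25 and 1.02 (SE 0.11, 0.09, 0.07 and 0.07). The median log2 fold change was 0.80 (limma camera adjusted p = 2.62e-17; adjusted p = 0.213 with an estimated correlation). Without LNP-GFP 3, 17 members rose and 0 fell. NK and T cell markers moved the same way as this list, with median log2 fold changes of 0.73 and 0.53, while fibroblast markers moved the other way (-1.33).

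**Figure D1:**
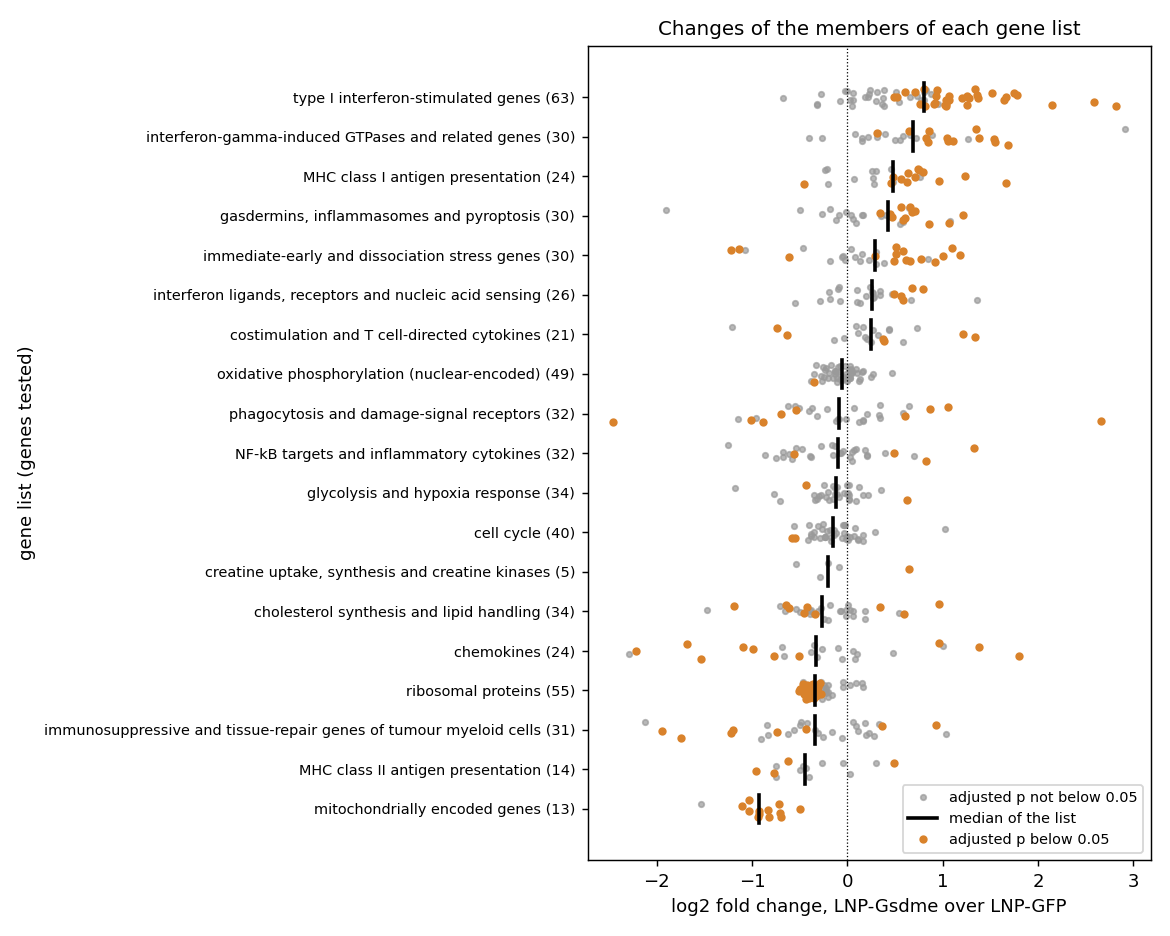
Log2 fold changes (horizontal axis, LNP-Gsdme over LNP-GFP) of the tested members of each functional and quality list (vertical axis, number tested in brackets). Each point is 1 gene, orange where the adjusted p was below 0.05, and the black bar is the list's median, from 0.80 for type I interferon-stimulated genes to -0.92 for mitochondrially encoded genes.

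The list of interferon-gamma-induced genes shifted in the same direction, and whether interferon gamma raised them was not tested. Of 30 tested, 13 rose, 0 fell and 17 did not pass (19 rose adjusted over the list alone). Their median log2 fold change was 0.69 (camera adjusted p = 1.28e-09; adjusted p = 0.213 with an estimated correlation). Gbp6 and Tgtp1, GTPases that act against intracellular pathogens, rose by 1.55 ± 0.09 and 1.06 ± 0.08 on the log2 scale, and Tgtp2, a near copy of Tgtp1, by 0.86 ± 0.10 (SE, n = 3 per group). Nos2, the inducible nitric oxide synthase, rose from 48.5 ± 1.08 to 124 ± 8.02 CPM (SD, n = 3; adjusted p = 0.00207). Of 26 genes for interferons, their receptors and nucleic acid sensors, Tlr3, Tlr9, Ifngr2, Aim2 and Tyk2 rose and 0 fell (8 and 1 adjusted over the list alone). The median of that list was 0.26 (camera adjusted p = 0.0123; adjusted p = 0.425 with an estimated correlation and 0.0537 by the rotation test fry; range over alternatives 0.000129 to 0.425). Without LNP-GFP 3 these counts of rises were 3 and 0. Ifng and Ifnb1 had log2 fold changes of 1.36 and -0.55 and did not pass over all genes (edgeR adjusted p = 0.0669 and 0.0622). NK cell markers, whose cells make interferon gamma, were higher in LNP-Gsdme by a median log2 fold change of 0.73 (camera adjusted p = 0.740 with an estimated correlation). That median was 0.46 without LNP-GFP 2 and 1.26 without LNP-GFP 1. Against LNP-GFP 1 alone it was 0.20, while the median of the interferon-gamma-induced genes was 0.56.

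MHC class I and class II genes went in opposite directions. Of 24 genes of class I antigen presentation, 12 rose and 1 fell (15 and 2 adjusted over the list alone). The median log2 fold change was 0.48 (camera adjusted p = 3.17e-05; adjusted p = 0.484 with an estimated correlation and 0.0537 by the rotation test fry; range over alternatives 4.20e-07 to 0.484). H2-T24, H2-T22 and H2-Q6, non-classical class I genes, rose by 1.67 ± 0.28, 1.23 ± 0.14 and 0.75 ± 0.09 on the log2 scale (SE, n = 3 per group). Reads of these genes may be shared within the family. Canx, the chaperone calnexin, fell by 0.46. Of 14 class II genes, H2-Aa, H2-Eb1 and Cd74 fell, Ifi30 rose and 10 did not pass (6 fell and 1 rose adjusted over the list alone). The median was -0.45 (camera adjusted p = 0.0185; adjusted p = 0.575 with an estimated correlation). H2-Aa went from 1557 ± 170 to 803 ± 136 CPM (SD, n = 3; adjusted p = 0.0172). Cd74, the invariant chain, went from 2910 ± 492 to 1883 ± 106 CPM (SD, n = 3; adjusted p = 0.0339). The markers of conventional dendritic cells, which carry much class II, were also lower by the preset correlation (median -0.48; adjusted p = 0.740 with an estimated correlation). Without LNP-GFP 3, 1 class I gene rose and 0 class II genes passed. The class II list lost its call without LNP-GFP 1 (adjusted p = 0.113) or LNP-Gsdme 3 (0.141) and by fry (0.158; range over alternatives 0.000236 to 0.575).

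Genes of pyroptosis and inflammasomes were higher as a group in LNP-Gsdme. Of 30 tested, 12 rose, 0 fell and 18 did not pass (17 rose adjusted over the list alone). Their median log2 fold change was 0.43 (camera adjusted p = 3.83e-05; adjusted p = 0.213 with an estimated correlation). Zbp1, a nucleic acid sensor that also stands in the type I interferon list, rose by 1.07 ± 0.12 on the log2 scale, and Casp8, an apoptosis initiator that also cleaves gasdermins, by 0.56 ± 0.07 (SE, n = 3 per group). Il18, a cytokine that inflammasomes mature, rose by 1.21 ± 0.17 on the log2 scale (SE, n = 3 per group; adjusted p = 0.0140). Gsdmd, Casp1 and Pycard rose as well, by 0.71, 0.68 and 0.86. Without LNP-GFP 3, 1 member of the list rose.

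Of 5 tested genes of creatine uptake, synthesis and phosphorylation, Ckb, the brain-type creatine kinase, rose and the other 4 did not pass (1 adjusted over the list alone). Ckb went from 145 ± 16.8 to 228 ± 7.22 CPM (SD, n = 3; log2 fold change 0.65 ± 0.10 SE, adjusted p = 0.0162). Its adjusted p was 0.0986 without LNP-GFP 3, in a range of 1.33e-06 to 0.124 over the alternatives. Slc6a8, the creatine transporter, stood at 57.6 ± 12.0 and 39.6 ± 6.74 CPM (SD, n = 3; log2 fold change -0.54, adjusted p = 0.114). Without LNP-GFP 1 it passed (adjusted p = 0.0381), and over the alternatives its adjusted p ran from 0.0381 to 0.788 and its log2 fold change from -0.69 to -0.15. The list's median was -0.20 (camera adjusted p = 0.708).

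**Figure D2:**
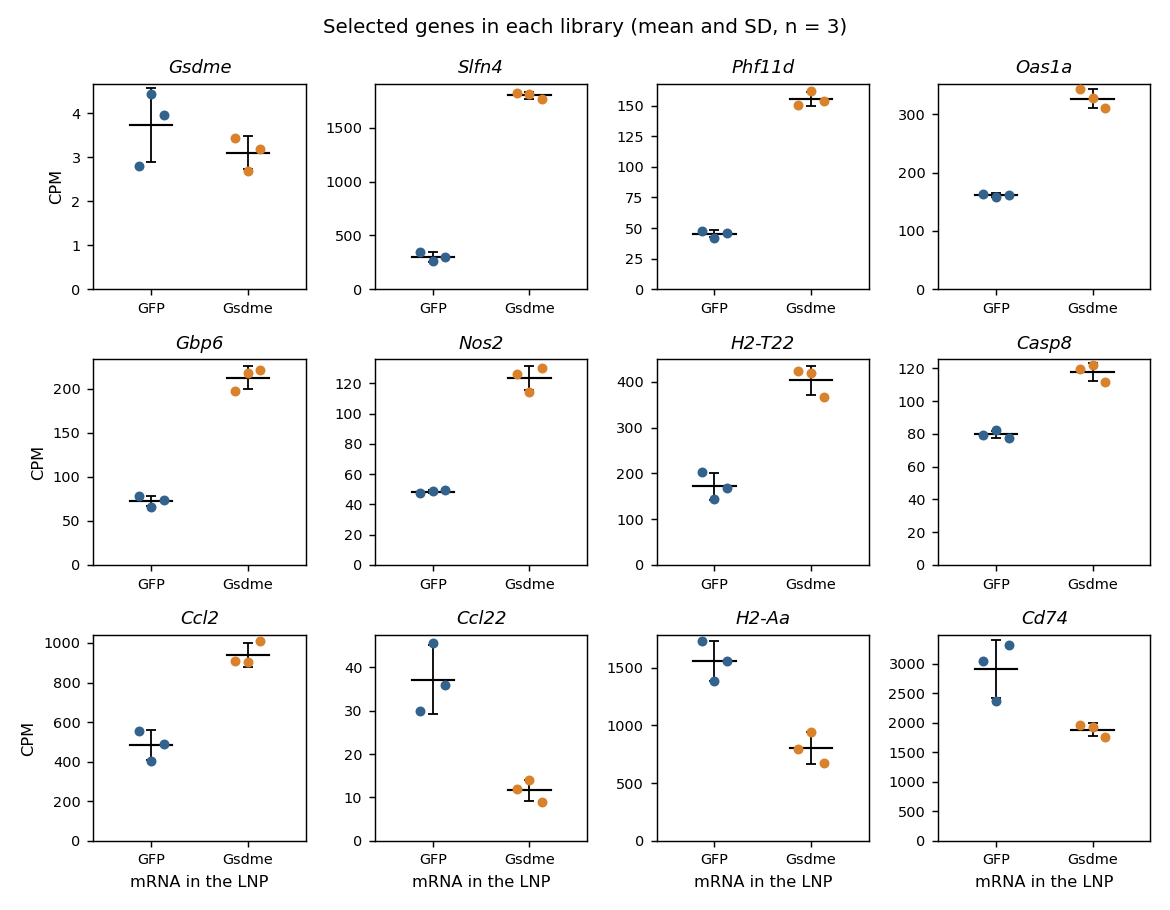
CPM (vertical axis, from 0) of 12 named genes in each library, with LNP-GFP in blue and LNP-Gsdme in orange; the horizontal line is the mean and the bar 1 SD (n = 3). The genes were picked for the plot after their values were seen, and all except Gsdme separate the groups, with Slfn4 at 299 against 1802 CPM.

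Chemokine genes moved both ways. Ccl2, which draws monocytes, rose from 483 ± 76.1 to 940 ± 59.6 CPM (SD, n = 3; adjusted p = 0.0120), as did Ccl12 and Cxcl11. Ccl22, which draws regulatory T cells, went from 37.1 ± 7.94 to 11.6 ± 2.49 CPM (SD, n = 3; adjusted p = 0.0116), and Cxcl14 fell by 1.53 on the log2 scale. In all, 3 of 24 rose and 7 fell (4 and 9 adjusted over the list alone), and without LNP-GFP 3 0 rose and 1 fell. The median log2 fold change was -0.33 (camera adjusted p = 0.0378; adjusted p = 0.295 with an estimated correlation). The list's call was lost without LNP-GFP 2 (adjusted p = 0.0688), LNP-GFP 3 (0.0630) or LNP-Gsdme 2 (0.0584), with upper-quartile factors (0.0612) and with a stricter filter (0.0518; range over alternatives 0.0207 to 0.295). Of 31 immunosuppressive and tissue-repair genes of tumour myeloid cells, 6 fell and 2 rose (12 and 3 adjusted over the list alone), and without LNP-GFP 3 0 fell and 1 rose. Its median was -0.34 (camera adjusted p = 0.0378; adjusted p = 0.294 with an estimated correlation). Its falling members included the matrix metalloprotease Mmp14 (log2 fold change -1.20 ± 0.14 SE) and the matrix protein Fn1 (-1.95 ± 0.26 SE), both of which fibroblasts express as well. Its rising members were Lgals9, which encodes galectin-9 (0.93 ± 0.08 SE), and Cd274, which encodes PD-L1 (0.36). That list's call was lost without LNP-Gsdme 2 (adjusted p = 0.0958) or LNP-Gsdme 3 (adjusted p = 0.132; range over alternatives 0.00418 to 0.294).

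Costimulatory molecules and T cell-directed cytokines had a median log2 fold change of 0.24 (camera adjusted p = 0.0242; adjusted p = 0.425 with an estimated correlation). Of 21 tested, Il18, Il18bp, Tnfsf14 and Tnfsf9 rose and Tnfsf4 and Il12b fell (7 rose and 2 fell adjusted over the list alone), and without LNP-GFP 3 0 passed. The call was lost without LNP-GFP 1 (adjusted p = 0.0531) or LNP-Gsdme 2 (0.0584) and by fry (0.0774; range over alternatives 0.00637 to 0.425). Targets of NF-kB and inflammatory cytokines did not shift as a group (median -0.10, camera adjusted p = 0.411). Of its 32 genes, Nfkbie, Osm and Zfp36 rose and Nfkb1 fell (5 and 5 adjusted over the list alone), and without LNP-GFP 3 1 rose and 0 fell. Nfkbie, an NF-kB inhibitor, stood at 1.32 ± 0.14 and Nfkb1 at -0.56 ± 0.07 on the log2 scale (SE, n = 3 per group). Phagocytosis and damage-signal receptors did not shift either (median -0.09, camera adjusted p = 0.646). In that list 4 of 32 rose, namely Tlr4, Cd300lf, Fcgr1 and Mertk, and 5 fell, among them Cd36 and Cd14 (5 and 8 adjusted over the list alone), against 1 and 0 without LNP-GFP 3.

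Transcripts of ribosomal proteins and of the mitochondrial genome were lower in LNP-Gsdme. Of 55 ribosomal protein genes, 28 fell and 0 rose (41 fell adjusted over the list alone). Their median log2 fold change was -0.34 (camera adjusted p = 1.52e-12; adjusted p = 0.213 with an estimated correlation). Rps4x stood at -0.50 ± 0.06 and Rpl5 at -0.46 ± 0.06 (SE, n = 3 per group). Of 13 mitochondrially encoded genes, 12 fell (13 adjusted over the list alone). Their median was -0.92 (camera adjusted p = 2.67e-10; adjusted p = 0.213 with an estimated correlation). The log2 fold change of mt-Nd3 was -0.94 ± 0.07 and that of mt-Nd5 -0.92 ± 0.08 (SE, n = 3 per group). Mitochondrial transcripts, whose share is also a measure of RNA and cell quality, made up 2.02, 2.41 and 2.17% of counts in LNP-GFP 1 to 3. In LNP-Gsdme 1 to 3 they made up 1.30, 1.32 and 1.61% (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows). Ribosomal protein transcripts made up 1.32 to 1.37% of counts in LNP-GFP and 1.07% in each LNP-Gsdme library (exact permutation p = 0.1). Nuclear genes of oxidative phosphorylation had a median of -0.06 and did not shift as a group (camera adjusted p = 0.206). Atp5b was the only 1 of 49 to pass (-0.35 ± 0.07 SE; 0 passed adjusted over the list alone). Without LNP-GFP 3, 4 mitochondrial genes and 0 ribosomal protein genes passed.

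The lists of lipid and cell cycle genes had medians slightly below 0. Of 34 genes of cholesterol synthesis and lipid handling, 6 fell and 3 rose (9 and 3 adjusted over the list alone), and without LNP-GFP 3 0 passed. The median log2 fold change was -0.26 (camera adjusted p = 0.0255; adjusted p = 0.213 with an estimated correlation). The call was lost without LNP-Gsdme 3 (adjusted p = 0.0983; range over alternatives 0.00973 to 0.213). Apoe, the lipid carrier apolipoprotein E, fell by 1.19 ± 0.15 and Abcg1, a cholesterol exporter, rose by 0.60 ± 0.08 (log2 scale, SE, n = 3 per group), with Ch25h and Plin2 also higher. Of 40 cell cycle genes, Mki67 and Cdc20 fell and 38 did not pass (0 passed adjusted over the list alone or without LNP-GFP 3). Their summed levels were 1531 ± 228 and 1538 ± 23.4 CPM (SD, n = 3), and the median was -0.15 (camera adjusted p = 0.0452; adjusted p = 0.647 with an estimated correlation). That call was lost without LNP-GFP 1 (adjusted p = 0.561), LNP-Gsdme 1 (0.108) or LNP-Gsdme 2 (0.170), with library sizes only (0.0678), with no filter (0.0581) and by fry (0.322; range over alternatives 1.57e-05 to 0.647). Of 34 genes of glycolysis and the hypoxia response, Mxi1 rose and Vegfa fell (both also adjusted over the list alone, and 0 passed without LNP-GFP 3), with a median of -0.12 and no shift as a group (camera adjusted p = 0.129; 0.0453 without LNP-Gsdme 1, range over alternatives 0.0453 to 0.630).

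Immediate-early and dissociation stress genes, which respond to tissue handling, also differed. Of 30 tested, 12 rose and 3 fell (15 and 5 adjusted over the list alone), with a median log2 fold change of 0.29 (camera adjusted p = 0.00408; adjusted p = 0.408 with an estimated correlation). Ier5 and Atf3 rose by 0.92 ± 0.08 and 0.77 ± 0.09 on the log2 scale (SE, n = 3 per group), as did Fos, while the 3 that fell, Hspa1a, Hspa1b and Hsph1, encode heat shock proteins. Without LNP-GFP 3, 1 rose and 0 fell.

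Markers of several other cell types differed between the sorted fractions. Fibroblast markers were lower in LNP-Gsdme, with 8 of 15 falling (12 adjusted over the list alone), and 0 falling without LNP-GFP 3. Their median log2 fold change was -1.33 (camera adjusted p = 1.16e-05; adjusted p = 0.740 with an estimated correlation). Col3a1, a collagen, fell from 3233 ± 270 to 1069 ± 553 CPM (SD, n = 3), while Col1a1 stood at 3364 ± 159 and 1381 ± 703 CPM and did not pass (adjusted p = 0.0567). Melanoma markers had a median of -1.64 (camera adjusted p = 0.00151; adjusted p = 0.740 with an estimated correlation), but only Kit of 15 passed (1 adjusted over the list alone). Dct, a pigment enzyme, stood at 82.2, 552 and 313 CPM in LNP-GFP 1 to 3 and at 23.1, 35.5 and 194 CPM in LNP-Gsdme 1 to 3. Tyrp1, another pigment enzyme, stood at 86.7, 511 and 310 against 28.1, 44.2 and 216 CPM. Against LNP-GFP 1 alone, a comparison added after the data were seen, the melanoma median was 0.02 (adjusted p = 0.306; range over alternatives 2.13e-05 to 0.740). Endothelial markers were lower (median -0.63, camera adjusted p = 0.00151; adjusted p = 0.740 with an estimated correlation). Of 14, Vwf and Ptprb fell (6 adjusted over the list alone), with Pecam1 and Kdr not passing (log2 fold changes -0.42 and 0.29). Erythroid and platelet markers had a median of -1.22 (camera adjusted p = 0.0218; adjusted p = 0.740 with an estimated correlation). Pf4 and Ppbp fell among 8 (2 adjusted over the list alone). Without LNP-GFP 3 0 melanoma, endothelial and erythroid markers passed, and by the rotation test fry 0 marker lists passed (lowest adjusted p 0.0665). The erythroid list's call was lost without LNP-GFP 2 (adjusted p = 0.0528) or LNP-Gsdme 2 (0.0749), with no filter (0.196) and against LNP-GFP 1 alone (0.434, median 0.52; range over alternatives 0.00545 to 0.740).

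NK and T cell markers were higher in LNP-Gsdme than in LNP-GFP as groups, and lowest in LNP-GFP 2. NK cell markers had a median log2 fold change of 0.73 (camera adjusted p = 0.00151; adjusted p = 0.740 with an estimated correlation), and Gzma rose among 13 (2 adjusted over the list alone; 0 without LNP-GFP 3). Gzmb, another granzyme, stood at 268, 54.2 and 155 against 359, 310 and 275 CPM, and Nkg7 at 115, 31.6 and 69.7 against 136, 130 and 94.5 CPM, and neither passed. T cell markers had a median of 0.53 (camera adjusted p = 0.00541; adjusted p = 0.791 with an estimated correlation) and 0 of 21 passed, by the test over all genes or adjusted over the list alone. Among them Thy1 and Il7r had log2 fold changes of 0.40 and -0.22. Against LNP-GFP 1 alone the T cell median was -0.01 (adjusted p = 0.820; range over alternatives 0.000113 to 0.820) and the NK cell median 0.20 (adjusted p = 0.322; range 5.38e-05 to 0.740). Without LNP-GFP 1 the T and NK cell medians were 0.90 and 1.26, and without LNP-GFP 2 they were 0.24 and 0.46. Conventional dendritic cell markers had a median of -0.48 (camera adjusted p = 0.0315; adjusted p = 0.740 with an estimated correlation). Among 17, Cd209a, Itgae, Mgl2 and Xcr1 fell and Dpp4 and Kmo rose (9 and 2 adjusted over the list alone), against 1 and 0 without LNP-GFP 3, and Naaa and Wdfy4 did not pass (0.58 and 0.23). That call was lost without LNP-GFP 1 (adjusted p = 0.102) or LNP-Gsdme 3 (adjusted p = 0.0821), with upper-quartile factors (0.0564) and by fry (0.0665; range over alternatives 0.00465 to 0.740).

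**Figure D3:**
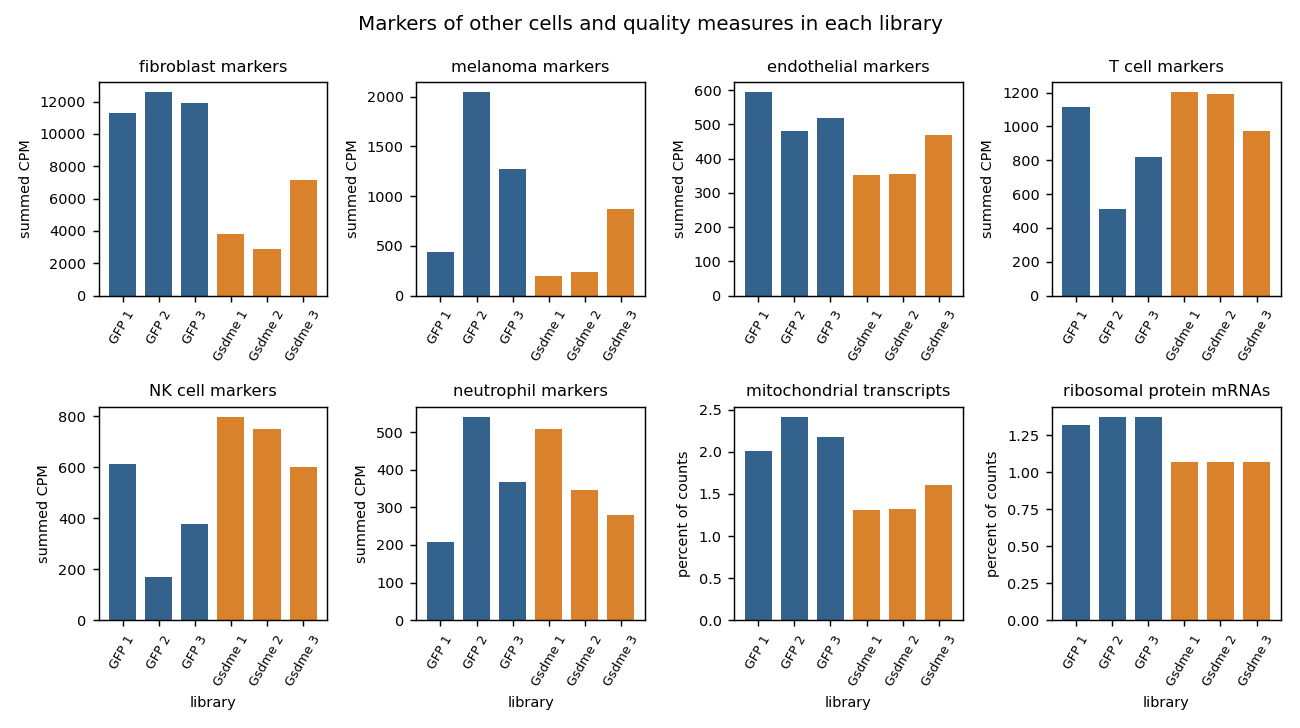
Summed CPM of the markers of 6 other cell types and the percent of counts from mitochondrial and ribosomal protein genes (vertical axes, from 0) in each library (horizontal axis), with LNP-GFP in blue and LNP-Gsdme in orange. Fibroblast markers stood at 11312 to 12561 CPM in LNP-GFP and 2894 to 7162 CPM in LNP-Gsdme, and melanoma, T, NK and neutrophil markers in LNP-GFP 3 lay between those of LNP-GFP 1 and LNP-GFP 2.

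The remaining marker lists did not shift. Macrophage markers had a median of -0.19 (camera adjusted p = 0.473; 0.0274 without LNP-GFP 2, range over alternatives 0.00111 to 0.919). Among 18, Apoe, Cd63, Cd81 and Pf4 fell and Maf and Mertk rose (6 and 3 adjusted over the list alone), and 0 passed without LNP-GFP 3, as in the neutrophil and plasmacytoid dendritic cell lists. C1qb, a complement component, stood at 841 ± 230 and 841 ± 29.7 CPM (SD, n = 3). Neutrophil markers had a median of -0.06 but a mean of 0.13 and a camera direction upwards (adjusted p = 0.474; 0.0397 without LNP-GFP 2, range over alternatives 1.03e-05 to 0.920). Elane, with counts near 0, rose among 17 (1 adjusted over the list alone). S100a9 stood at 15.5, 116 and 65.6 against 108, 50.3 and 30.8 CPM, and Csf3r not passing (0.38). Plasmacytoid dendritic cell markers were not called (median -0.35, camera adjusted p = 0.513), and 1 rose and 1 fell among 12 (1 and 2 adjusted over the list alone). B cell markers (median -0.31, adjusted p = 0.559) and mast cell, basophil and eosinophil markers (median -0.34, adjusted p = 0.731) were not called either, and 0 of 6 and 0 of 7 passed, also adjusted over the list alone. Their most abundant members did not pass: Lair1 and Runx2 had log2 fold changes of 0.98 and -0.14, Ebf1 and Ighm -0.59 and -0.02, and Gata2 and Ear2 -0.99 and -0.39. Ly6C-low monocyte markers had a median of 0.03 (camera adjusted p = 0.870), with Cd36 falling by 1.01 and Cebpb rising by 0.35 on the log2 scale.

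The LNP-GFP libraries were less alike than their group means show. Over genes more than 4-fold apart between LNP-GFP 1 and LNP-GFP 2 and above 10 CPM in either, 73 of 79 had a level in LNP-GFP 3 between both. The median share was 0.499 of the way. The count alone is no sign of a mix, because genes picked as far apart in 2 libraries can hold another between them. LNP-Gsdme 3 lay between LNP-GFP 1 and 2 in 67 of the same 79 genes, although LNP-Gsdme 1 and 2 did in only 23 and 24. A weighted mean with a share of 0.48 for LNP-GFP 1 left a median squared residual of 1.96 times that of counting noise in LNP-GFP 3. The SDs of the LNP-GFP group over n = 3 depend on this library being a separate sample.

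**Figure D4:**
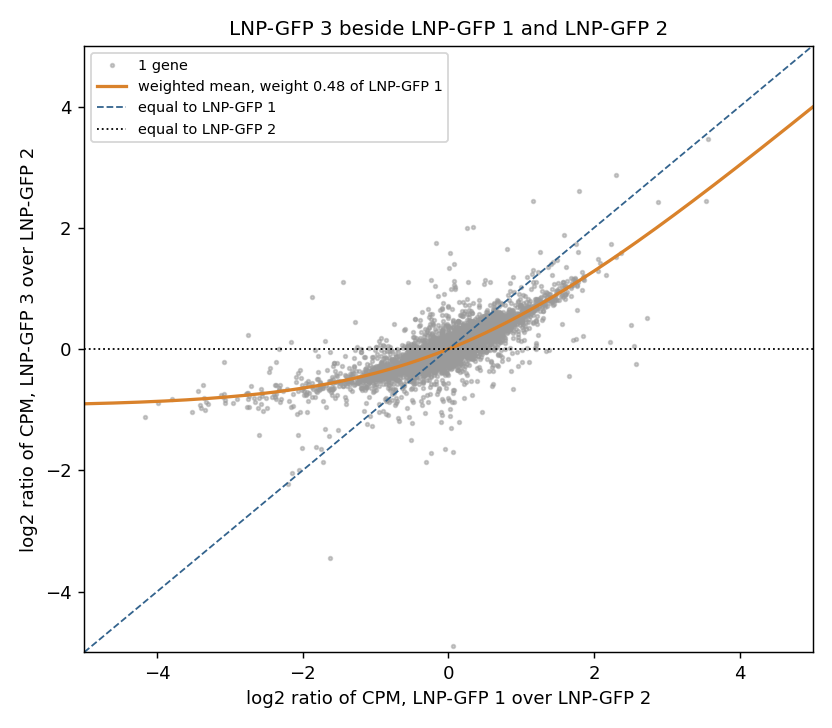
Log2 ratio of CPM of LNP-GFP 3 over LNP-GFP 2 (vertical axis) against that of LNP-GFP 1 over LNP-GFP 2 (horizontal axis), for 9571 tested genes of at least 10 CPM in LNP-GFP 1 or 2, of which 5 lie outside the axes. The orange curve is the weighted mean with a share of 0.48 for LNP-GFP 1, which left a median squared residual of 1.96 times that of counting noise. The broken and dotted lines mark levels equal to LNP-GFP 1 and LNP-GFP 2.

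Calls in the lists rest on the preset correlation of camera. With an estimated correlation 0 of the functional and quality lists and 0 of the marker lists passed (lowest adjusted p 0.213 and 0.740), and by the rotation test fry 9 and 0 passed. Leaving out LNP-GFP 2, LNP-GFP 3, LNP-Gsdme 1 or LNP-Gsdme 2 brought the count of genes that rose to 594, 64, 107 or 119, and leaving out LNP-GFP 1 brought it to 1625.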

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

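The comparison of LNP-GFP 1 alone was chosen after the result was seen; the other alternatives were planned. No result called in the main fit turned past the test in the opposite direction. The neutrophil list, not called in the main fit, had a median of -0.06 there. Without LNP-GFP 2 it was called with a median of 0.41 (camera adjusted p = 0.0397). DESeq2 gave 1543 genes higher and 1505 lower (1558 adjusted p not given), an adjusted p below 0.01 left 131 and 52, and a 2-fold minimum left 226 and 288. Leaving out 1 library gave 64 to 1625 genes higher, 24 to 1216 lower and 17 to 36 type I interferon-stimulated genes higher. The lowest came without LNP-GFP 3 (64 and 24); without LNP-GFP 1 they were 1625 and 1216, without LNP-GFP 2 594 and 353, without LNP-Gsdme 1 107 and 46, without LNP-Gsdme 2 119 and 68, and the falls without LNP-Gsdme 3 1201. The lists called ran from 10 to 14 and, for markers, from 6 to 8. With the replicate block, 103 genes were higher, 52 lower and 23 type I genes higher. Same-numbered libraries deviated from their group means with correlations of 0.21, -0.24 and 0.03, and not every library correlated best with its own number. With 3 libraries per group and LNP-GFP 3 midway between the other controls, these values cannot tell whether samples were paired. The labels do not state a pairing. LNP-GFP 1 alone gave 8 genes higher, 4 lower (Thbs4, Nek7, Cilp and Gm49322) and 2 type I genes higher (Slfn4 and Phf11d), with 1 control assumed to vary like the LNP-Gsdme group. Against it the medians of melanoma (0.02), T cell (-0.01) and erythroid markers (0.52) lost their direction, and the neutrophil median went from -0.06 to 1.97. With an estimated correlation 0 of 14 called functional and quality lists and 0 of 7 marker lists passed, the type I list among them (median 0.80, adjusted p = 0.213), and fry passed 9 and 0. Upper-quartile factors gave 855 higher and 1055 lower. Of 75 named genes called, 28 passed without LNP-GFP 3. All 75 kept their direction, which their lack of overlap between the groups made all but certain. The cause of these shifts was not tested. Counting depth limits genes near 1 CPM.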

Other observations

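The tests of LNP-GFP 3 as a mix, of carry-over of other cells and of what accompanied the interferon-stimulated genes were chosen after the results were seen; the counts over splits of the libraries were planned. Members of the type I interferon list that did not pass included Rsad2, Ifit1 and Cxcl10, while Isg15, Irf7, Oas2 and Oas3 rose by log2 fold changes of 1.04, 1.52, 0.93 and 1.36. Rsad2, which encodes viperin, stood at 640, 1489 and 1060 CPM in LNP-GFP 1 to 3 and at 1113, 1145 and 932 CPM in LNP-Gsdme 1 to 3 (log2 fold change 0.00, edgeR quasi-likelihood adjusted p = 0.999). Ifit1, which binds viral RNA, stood at 146, 511 and 328 against 210, 228 and 176 CPM (-0.68, adjusted p = 0.298), and Cxcl10, a chemokine for T cells, had a log2 fold change of 0.05 (adjusted p = 0.802). Ifnb1, which encodes interferon beta, stood at 17.1, 17.3 and 20.3 against 14.3, 10.2 and 12.9 CPM (-0.55, adjusted p = 0.0622). The 31 members that did not pass had a median log2 ratio of 0.57 over LNP-GFP 1, 0.00 over LNP-GFP 2 and 0.28 over LNP-GFP 3, and the 32 that passed 1.16, 1.23 and 1.07. A test of whether high levels in LNP-GFP 2 and 3 held these members back was run and set aside, because it sorted members by the outcome: against LNP-GFP 1 alone their median was 0.58, and that of the members that passed 1.18.

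Markers of Ly6C-high monocytes moved apart from each other. Of 18 tested, 6 rose, among them Ly6c2, Ly6c1, Ms4a4c, Plac8 and Fcgr1, and 3 fell (Fn1, Cd177 and Vcan), with 7 and 5 adjusted over the list alone, and without LNP-GFP 3 3 rose and 1 fell. Plac8 rose by 0.89 on the log2 scale (adjusted p = 0.0214), while Vcan, a matrix proteoglycan, fell by 0.92 (adjusted p = 0.0271). Lyz2, the abundant lysozyme of myeloid cells, stood at 3646 ± 494 and 2683 ± 491 CPM (SD, n = 3; adjusted p = 0.120). The list as a whole was not called, its median of -0.21 and its mean of 0.13 differing in sign (camera direction upwards, adjusted p = 0.474). Of 12 Ly6C-low monocyte markers, Nr4a1, Clec4a3 and Cebpb rose and Cd36 and Treml4 fell (3 and 3 adjusted over the list alone), and without LNP-GFP 3 0 passed. These genes and those of the preceding paragraph, apart from Ly6c2, Fn1, Lyz2, Cd36 and Cebpb, were chosen after their values were seen.

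LNP-GFP 3 lay midway between LNP-GFP 1 and LNP-GFP 2. Predicted as a mix of both at a share of 0.48, it left a median squared residual of 1.96 times that of counting noise. This was the smallest of the 60 ways to predict 1 library from 2 others, the next being 3.40. That LNP-GFP 3 holds RNA of both other samples is a hypothesis consistent with this value and with shares of 0.482, 0.512, 0.471 and 0.523 for the summed melanoma, T, NK and neutrophil markers. These are the 4 lists over 2-fold apart between LNP-GFP 1 and LNP-GFP 2, a choice made after the values were seen, and over the lists closer together, where a share is poorly defined, it ran from 0.175 to 24.4. An independent sample of intermediate cell makeup stays open. The squared residual was 0.578 of the next best and not under 0.5 of it, but this ratio cannot decide the question. The next best predicted LNP-Gsdme 1 from LNP-Gsdme 2 with a share of only 0.07 for LNP-GFP 3, so it reflects how alike those LNP-Gsdme libraries were. If the library were a mix, its counts could not stand as a separate control, and without it 64 genes were higher and 24 lower.

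Fibroblast and melanoma markers were lower in LNP-Gsdme by camera with the preset correlation. Neither list passed with an estimated correlation (adjusted p = 0.740 for each) or by fry (0.102 and 0.222). Of the fibroblast markers 11 of 15 lay within 0.5 of their median log2 fold change of -1.33 (median absolute deviation 0.208) and of the melanoma markers 11 of 15 within 0.5 of -1.64 (0.397), as a smaller carry-over of those cells or their RNA may produce. The sort for CD11b and Ly6C is meant to remove both cell types, but their transcripts were present. The summed fibroblast markers stood at 11312 to 12561 CPM in LNP-GFP and 2894 to 7162 CPM in LNP-Gsdme. The summed Ly6C-high monocyte markers stood at 10548 to 11310 CPM and 9726 to 11544 CPM. Sums over different genes do not give shares of cells. Of the most abundant genes, Col1a1 stood at 3364 and 1381 CPM and Dct at 316 and 84.2 CPM. Neither passed (edgeR adjusted p = 0.0567 and 0.230), and the groups overlapped for Dct. Farther off were Thy1 (0.40, also in the T cell list), Pdgfrb (-0.36), Pdgfra (-0.48) and Mmp2 (-2.07), and Cdh2 (-1.08), Kit (-0.82), Mitf (-0.65) and Ednrb (-0.50), so 1 factor does not cover either list. A change of the tumour by LNP-Gsdme that left fewer such cells stays open and was not tested, and against LNP-GFP 1 alone the melanoma median was 0.02.

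Type I interferon-stimulated genes were higher in LNP-Gsdme (median log2 fold change 0.80), and a response of the monocytes is an untested hypothesis beside the open explanations. T cells as the source stay open. Against LNP-GFP 1 and 3 the T cell median of 0.24 lay 0.600 below the interferon median of 0.84. That is past the bound of 0.5 and the spread of 0.150, which is a spread between markers and not between libraries. This cannot exclude T cells, because equal numbers of them with more interferon-stimulated transcripts would not need their markers to rise. The difference passed the bound only with LNP-GFP 2, the control with the fewest T cell transcripts, left out. With all libraries it was 0.278. Against LNP-GFP 2 and 3 the T and NK cell medians of 0.90 and 1.26 exceeded the interferon median of 0.64 (differences of -0.261 and -0.616), so NK cells stay open there too. NK cells also stay open against LNP-GFP 1 and 3, where their median of 0.46 lay 0.380 below the interferon median, within 0.5 and their spread of 0.398. Against LNP-GFP 1 alone, a single control library, the T, NK and interferon medians were -0.01, 0.20 and 0.98. The sort for high Ly6C is meant to remove T and NK cells that lack it. Gzmb stood at 268, 54.2 and 155 CPM in LNP-GFP 1 to 3 and at 359, 310 and 275 CPM in LNP-Gsdme 1 to 3. A larger share of monocyte RNA, left by less RNA of other cells, also stays open, since the monocyte markers lay 1.02 below the interferon median, past 0.5 but within their spread of 1.4, by a rule set after these values were seen.

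The 10 splits of the 6 libraries are too few for a share under 0.05: the real split, the 1 with most calls, gave 1859 called genes and 32 type I genes, and the highest of the others 2 and 0.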
